A study of Mus musculus with 6 samples.

How the data were processed

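RNA was measured in purified germ cells of C57BL/6 mice on Affymetrix MoGene 1.0 ST arrays, a single-colour platform that gives 1 value per transcript cluster. Pachytene spermatocytes, which are in meiotic prophase, and round spermatids, the haploid cells that follow meiosis, were taken from wild-type (WT) and Rnf8 knockout (KO) testes. Per the labels' protocols, cells from 3 to 4 males were separated by sedimentation at unit gravity, with a stated enrichment above 95%. Groups were taken from the sample titles: 2 WT pachytene, 2 KO pachytene, 1 WT round spermatid and 1 KO round spermatid array. The numbering of the titles has 2 further round spermatid arrays, which were not analysed here. No label says that arrays of a group came from separate animals or cell preparations, so p-values measure only the spread between these samples, which may be technical.

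The deposited values are intensity on a linear scale, made by the authors with Affymetrix Expression Console 1.1 and RMA, per the submitters' processing notes. Background, normalization and summary options are not given in the sources used here. The tests had been planned for log2 values, so log2 of the deposited intensity was taken before any test. Median intensity per array lay between 197 and 218. For arrays, their number limits the precision.

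The table holds 35556 transcript clusters. The platform annotation gave 1 gene symbol to 21789 of them and several symbols to 1621, and did not list 12146. By gene identifier, 21695 single-gene clusters matched a RefSeq table of the GRCm38.p6 assembly, which was used for names, chromosomes and the order of neighbouring genes, and no symbol needed an update. No coordinates are given, because the build behind the array values is not given in the sources used here. The single-gene clusters named 19938 genes, and for the 999 genes with more than 1 cluster the cluster of highest mean was used. Genes at log2 6 or more on at least 1 array were tested: 17925 genes, of which 624 lie on X, 9 on Y and 17214 on autosomes. The only cluster of Rnf8 also lists the readthrough gene Gm28043, so it was described outside the tests.

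Tests used limma 3.58.1 in R 4.3.3 on log2 values (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. A fit with 4 groups gave KO against WT in pachytene spermatocytes, round spermatids against pachytene spermatocytes in each genotype, and the interaction. It has 2 residual degrees of freedom, all from the pachytene arrays, so each lone round spermatid array is assumed to vary like them. An additive fit of genotype and cell type, with 3 residual degrees of freedom, gave the effect of genotype over both cell types and of cell type over both genotypes. KO against WT in round spermatids rests on 1 array each, so its main count uses no p-value, and the fit with 4 groups, which lends it the spread of the pachytene pairs, was run as an alternative. In the main count, genes differing at least 2-fold were counted, and the median of a gene list was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. The rise-matched random lists used 10 bins of the difference between the cell types. Spermatid-high genes are those at least 2-fold higher in round spermatids than in pachytene spermatocytes by the mean of both genotypes.

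The gene lists cover X-linked spermatid-expressed genes, X-linked widely expressed genes, Y-linked genes, autosomal retrogenes of X-linked parents, the DNA damage response, meiotic prophase, spermatid differentiation, histone variants, histone acetylation, the piRNA pathway, p53 targets, ribosomal proteins, oxidative phosphorylation, and markers of Sertoli cells, Leydig cells, spermatogonia, macrophages and blood, and peritubular and vessel cells. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Members not found among the single-gene clusters were not tested. These include Slx, Slxl1, Srsx, Ott and the H2al1 genes of the X-linked spermatid-expressed list, and Sly, Ssty1, Ssty2 and Rbmy of the Y-linked list. Cypt12, a tested member of the X-linked spermatid-expressed list, lies on chromosome 3 in the reference. The lists, the tests and the rule for named genes were fixed before the data were examined. That rule takes Rnf8, the 10 genes with the largest log2 fold change in each direction per tested comparison among those past the threshold whose arrays do not overlap between the groups, filled where fewer pass with the largest changes among genes whose arrays do not overlap. It takes the 12 largest differences in each direction for the round spermatid arrays and up to 4 members of each list. Autosomal clone or predicted names and olfactory or vomeronasal receptors are counted but not named.

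The scripts were tested on simulated data, with 200 of 17925 genes changed and independent normal noise of the spread fitted to the real arrays. No outlying array and no correlation between genes were simulated. The shares recovered may therefore be too high for the real arrays, and an absence of calls there does not show that few genes changed. Of genes changed 2-fold, 89.6% were recovered for KO against WT in pachytene spermatocytes, 97.0% for genotype over both cell types and 97.0% for cell type. For 1.5-fold changes these shares were 22.4%, 49.3% and 46.3%, and for 4-fold changes 100% in each. Unchanged genes were called as well, 16, 18 and 21 of them, or 10.2%, 9.89% and 11.5% of the calls, above the 5% that the threshold stands for. Choosing spermatid-high genes by both genotypes gave a median KO minus WT difference of -0.0026 with no effect simulated, against -0.0598 when they were chosen by WT alone. Alternatives covered the intensity floor, a second quantile normalization, centring on the autosomal median, the use of every cluster, the prior of limma, thresholds, replicate blocks, the correlation within lists and leaving out each array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.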

Results

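Transcript levels were measured on 6 arrays of purified mouse spermatogenic cells from wild-type and Rnf8 knockout males. Rnf8 encodes a ubiquitin ligase that modifies histones at DNA damage sites and on the sex chromosomes of meiotic cells. There were 2 arrays each of WT and KO pachytene spermatocytes, and 1 array each of WT and KO round spermatids. The design asks what the loss of Rnf8 does to transcript levels in each cell type, and how the X and Y chromosomes, which are silenced in pachytene spermatocytes, compare with autosomes in round spermatids. The first principal component of the tested genes held 77.7% of the variance and separated the cell types.

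The array has 1 cluster for the targeted gene, and that cluster lists both Rnf8 and the readthrough gene Gm28043. Its log2 intensity was 8.69 ± 0.25 (SD, n = 2) in WT and 7.95 ± 0.13 (SD, n = 2) in KO pachytene spermatocytes, a difference of -0.74, or 1.67-fold. In round spermatids it was 7.78 in WT and 7.50 in KO, a difference of -0.28. Both KO pachytene arrays lay below both WT arrays. Where the cluster lies relative to the deleted part of the gene is not given in the sources used here, so it is a limited check of the labels.

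Round spermatids differed widely from pachytene spermatocytes. In the additive limma fit, 6255 of 17925 genes passed an adjusted p of 0.05, with 3191 higher and 3064 lower in round spermatids. Decorin (Dcn), a matrix proteoglycan, rose by 2.86 on the log2 scale (SE 0.21, 2 against 4 arrays), Samt2b by 2.47, the metalloprotease-disintegrin genes Adam25 and Adam39 by 2.37 and 2.28, granzyme N (Gzmn) by 2.31, Btg1b by 2.26, Iqcf4 by 2.24, the beta-defensin Defb14 by 2.23, Cfap47 by 2.22 and the contactin Cntn6 by 2.22. Zfp389 fell by 4.24 (SE 0.11). Further falls were -3.12 for Hsd3b6, -3.06 for the Sin3 complex member Sap30, -2.98 for Wdfy3, -2.91 for the POU factor Pou5f2, -2.78 for the testis linker histone H1f6, -2.66 for Zfp346, -2.65 for Tdrd5, -2.64 for Cyp17a1 and -2.57 for Lypd10. Among these 20 genes the highest adjusted p was 0.00161, for Cfap47. The count rests on the spermatid arrays: it was 3577 without the KO and 2786 without the WT round spermatid array.

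More genes of X and Y passed as higher than as lower. Of 624 X-linked genes, 251 (40.2%) passed as higher in round spermatids and 14 as lower, against 2920 higher and 3038 lower of 17214 on autosomes. On Y, 7 of 9 genes rose. Median log2 differences were 0.20 for X, 1.39 for Y and -0.06 for autosomes. In the list of X-linked spermatid-expressed genes, 25 of 28 rose (26 adjusted over the list alone), among them Akap14 by 1.93, Tex13a by 1.90, the cylicin gene Cylc1 by 1.89 and Actrt1 by 1.81. Of the X-linked widely expressed genes, 35 of 58 rose (38 adjusted over the list alone). Of 8 Y-linked genes on the list, 6 rose (6 adjusted over the list alone), with the zinc finger gene Zfy1 at 2.04, Eif2s3y at 1.79, the ubiquitin-activating enzyme gene Uba1y at 1.52 and the deubiquitinase gene Usp9y at 1.42. With camera, adjusted p was 7.51e-13, 7.87e-11 and 0.00195 for these 3 lists, and adjusted p = 0.389, 0.379 and 0.389 with an estimated correlation.

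**Figure D1:**
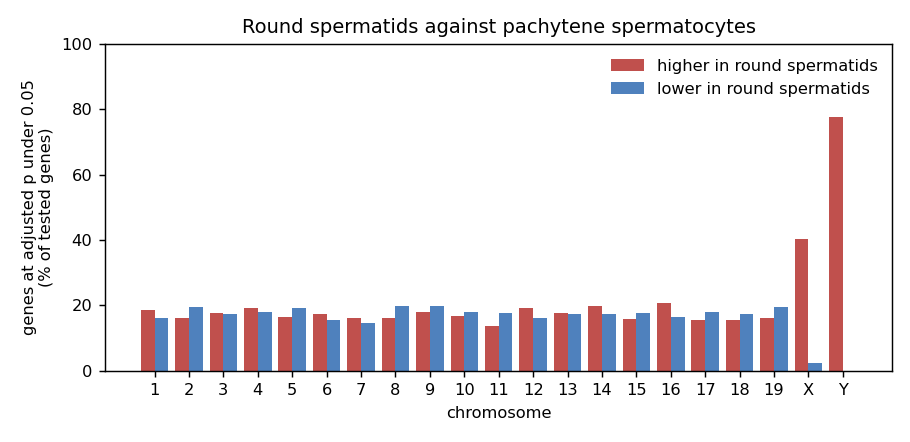
Bars give, for each chromosome, the share of tested genes (%) that passed an adjusted p of 0.05 as higher (red) or lower (blue) in round spermatids than in pachytene spermatocytes, over both genotypes (2 against 4 arrays). X has 40.2% higher and 2.24% lower, and Y has 77.8% higher, while autosomes lie between 13.6% and 20.7% higher.

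Spermatid differentiation genes rose as well: 41 of 62 rose and 1 fell (42 and 1 adjusted over the list alone), with the calmodulin-dependent kinase Camk4 at 1.87, the sperm calcium channel subunit Catsper3 at 1.85 and the lysozyme-like Lyzl4 at 1.68, while Gopc fell by 1.62. The camera adjusted p was 4.97e-13, and adjusted p = 0.389 with an estimated correlation. Of the spermatid markers, Tnp1, Tnp2 and Acrv1 rose by 1.27, 0.75 and 0.62. Prm1 at 0.22 and Prm2 at 0.23 did not pass in limma (adjusted p = 0.246 and 0.152). Both were already high on the pachytene arrays, Prm1 between 12.85 and 13.18 and Prm2 between 13.25 and 13.44. In round spermatids Prm1 lay at 13.23 in WT and 13.20 in KO and Prm2 at 13.56 and 13.51, near the highest values on these arrays. Whether that limited the rise was not tested. Whether the pachytene fractions held spermatid transcripts was not tested. Genes of the piRNA pathway, which silences transposons, moved down: 14 of 25 fell and 1 rose (15 and 1 adjusted over the list alone). Log2 differences were -2.65 for Tdrd5, -2.31 for Tdrd1, -2.03 for Piwil1 and -1.59 for Piwil2. The camera adjusted p was 1.51e-05, and adjusted p = 0.379 with an estimated correlation.

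Leydig and Sertoli markers also moved down. Of 14 Leydig markers, 10 fell (11 adjusted over the list alone), including the steroidogenic genes Hsd3b6 (-3.12), Cyp17a1 (-2.64), Cyp11a1 (-1.74) and Hsd17b3 (-1.70). Of 23 Sertoli markers, 11 fell and 1 rose (13 and 1 adjusted over the list alone), with Clu at -1.34, Gja1 at -1.20, Cst9 at -1.04 and Ctsl at -0.83. The camera adjusted p was 1.49e-06 for Leydig and 3.42e-04 for Sertoli markers, and adjusted p = 0.379 and 0.389 with an estimated correlation. Cyp17a1 lay between 11.26 and 11.92 on the pachytene arrays and at 8.70 in WT and 9.30 in KO round spermatids, and Hsd3b1 between 6.33 and 6.90 on the pachytene arrays and at 5.60 and 5.53 in round spermatids.

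The remaining lists had no camera adjusted p below 0.05. The DNA damage response had 8 genes up and 20 down of 47 (9 and 20 adjusted over the list alone), with the polycomb-related L3mbtl2 at -1.95, the Brca1 partner Bard1 at -1.51, Rad1 at -1.50 and the checkpoint kinase Chek1 at 1.33 (list adjusted p = 0.0726). Meiotic prophase genes had 11 up and 15 down of 39, and autosomal retrogenes 3 up and 2 down of 12. Ribosomal proteins had 2 up and 6 down of 55, oxidative phosphorylation 6 up and 12 down of 79, and p53 targets 3 up and 1 down of 28. Spermatogonial markers had 7 up and 2 down of 26, macrophage and blood markers 5 up and 0 down of 17, and peritubular and vessel markers 4 up and 1 down of 20, Dcn among the 4.

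Within each genotype, the same comparison passed 3577 genes in WT (2063 higher, 1514 lower) and 2786 in KO (1499 higher, 1287 lower). The X-linked genes Samt4 and Cenpi, a centromere protein gene, were among the 10 largest rises in WT, at 2.55 (SE 0.20) and 2.41 (SE 0.19). In KO, Samt4 rose by 1.06 (SE 0.20) and Cenpi by 1.26 (SE 0.19). The KO round spermatid value of Samt4 lay near the lower quartile of that array, log2 6.17, and its pachytene means lay lower still. The size of its rise is therefore uncertain in both genotypes. The interaction of genotype and cell type passed no gene in limma (130 genes at an unadjusted p under 0.05). Its most negative values were X-linked Fndc3c1 at -2.27 (SE 0.36) and 4930595M18Rik at -1.76 (SE 0.26), then Unkl at -1.66, Samt4 at -1.49, Rhox11 at -1.48 and Ssxb3 at -1.41, and its most positive was Zfp455 at 1.61. For Fndc3c1, 4930595M18Rik and Samt4 the KO round spermatid value lay near the lower quartile of that array, so their size and rank here are uncertain. The WT count was 1640 and 1404 without WT pachytene array 1 or 2 and 5511 without either KO pachytene array, and the KO count was 1646 without either WT pachytene array.

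In pachytene spermatocytes, no gene passed for KO against WT (limma, 430 genes at an unadjusted p under 0.05, smallest adjusted p 0.414). Among genes whose arrays did not overlap, and leaving out autosomal clone names, the 6 largest differences above WT were Malrd1 at 1.82 (SE 0.26, n = 2 per genotype), Tmem159 at 1.18, Zfa-ps at 1.13, Atp8b1 at 1.08, the small RNA gene Scarna13 at 1.01 and Il9 at 1.01. Below WT were the carboxypeptidase gene Cpn1 at -2.25 (SE 0.57), Y-linked Srsy at -2.24 (SE 0.24), X-linked Ppp4r3c-ps at -1.73, Zfp455 at -1.57, Tbc1d7 at -1.50, X-linked 4933400A11Rik at -1.47, the mitochondrial ribosomal gene Mrps21 at -1.25, X-linked 4921511C20Rik at -1.24 and Zfp943 at -1.24. Without WT pachytene array 1, 2 genes passed. With the replicate number as a block 43 genes passed (10 higher, 33 lower in KO). With the numbers crossed, a pairing chosen after the data were seen, 88 passed (18 higher, 70 lower). The values give no sign that the numbers pair the arrays: deviations of same-numbered arrays correlated at -0.23 across genes. With 2 arrays per genotype, that value cannot settle whether they do.

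No member of any list passed in pachytene spermatocytes over all genes. X-linked genes had a median difference of 0.06 and autosomal genes 0.03, and the X-linked set did not pass limma's camera test. Their difference of 0.0287 lay between 0.0037 (without KO array 2) and 0.0202 when each pachytene array was left out, and at 0.0076 with a second quantile normalization. With camera, X-linked spermatid-expressed genes lay lower in KO (median -0.14, 17 of 28 below WT, 1 higher and 2 lower adjusted over the list alone). Samt3 was at -1.21 and Samt4, at dim levels in both genotypes, at -0.68, but Akap14 at 0.81. The adjusted p was 3.69e-04, and adjusted p = 0.699 with an estimated correlation. Markers of spermatogonia (median 0.15, 23 of 26 above WT), Sertoli cells (0.12, 19 of 23) and peritubular and vessel cells (0.11, 17 of 20) and the X-linked widely expressed genes (0.07, 42 of 58) lay higher in KO, at adjusted p of 0.00186, 0.0361, 0.0480 and 0.0480. For each of these 4 lists, adjusted p = 0.699 with an estimated correlation. Leydig markers (median -0.09, 8 of 14 below WT) and the DNA damage response (-0.03, 26 of 47 below WT) lay lower, each at 0.0487, and adjusted p = 0.699 and 0.797 with an estimated correlation. In these 6 lists 0 members passed adjusted over the list alone. Leaving out an array changed these calls. Without KO pachytene array 2 the X-linked spermatid-expressed genes, peritubular and vessel markers and DNA damage response no longer passed, and without KO pachytene array 1 only the X-linked spermatid-expressed genes and the DNA damage response remained of the 7 lists. Without WT pachytene array 1 the spermatogonial markers no longer passed. Without WT pachytene array 2, and also with a second quantile normalization, Sertoli, Leydig, peritubular and vessel markers, the X-linked widely expressed genes and the DNA damage response no longer passed. KO pachytene array 2 stood apart on the second principal component, which held 12.6% of the variance, and its spermatid-high autosomal genes lay at -0.26 relative to the mean of the other 3 pachytene arrays, while those of KO pachytene array 1 lay at 0.33 relative to the mean of its other 3.

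Over both cell types, no gene passed for KO against WT (limma, 979 genes at an unadjusted p under 0.05, and 2 genes with a trended and robust prior). The smallest adjusted p was 0.0582, for Srsy, which lay at -2.18 (SE 0.18) with all 3 KO arrays below the WT arrays of the same cell type. Ppp4r3c-ps was at -1.92 (SE 0.20, adjusted p = 0.0756) and Samt3 at -1.42 (SE 0.19, adjusted p = 0.159). Il9 was at 1.05 (SE 0.10, adjusted p = 0.0742), Zfa-ps at 1.16 (SE 0.13, adjusted p = 0.104) and Malrd1 at 1.58 (SE 0.23, adjusted p = 0.190). Among X-linked spermatid-expressed genes, 0 passed over all genes, and 1 higher and 9 lower passed adjusted over the list alone (camera adjusted p = 1.78e-07, adjusted p = 0.497 with an estimated correlation). Markers of other cells moved with genotype in the same test: 25 of 26 spermatogonial (median 0.17), 19 of 20 peritubular and vessel (0.16) and 21 of 23 Sertoli markers (0.15) lay above WT, at adjusted p of 1.13e-04, 9.55e-04 and 0.0012, and adjusted p = 0.497 with an estimated correlation for each. DNA damage response genes had a median of -0.04, with 29 of 47 below WT (adjusted p = 0.00778, adjusted p = 0.579 with an estimated correlation). In these 4 lists 0 members passed over all genes or adjusted over the list alone. Without KO pachytene array 1, 21 genes passed, and without KO pachytene array 2, 4 genes passed.

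In round spermatids, 69 genes differed at least 2-fold between the KO and the WT array, 63 lower and 6 higher in KO. There was no replicate check, so this describes these 2 arrays, and in a limma fit that lends them the spread of the pachytene pairs 0 genes passed an adjusted p of 0.05. Of the 63 lower genes, 35 were X-linked, 1 Y-linked, 26 autosomal and 1 without an assigned chromosome. Chromosome 17, which holds Rnf8 and 849 of 17214 tested autosomal genes, had 8 of the autosomal lower genes and 2 of the 6 higher ones. No other autosome had more than 4 and 1. X-linked genes were 55.6% of the lower genes and 3.48% of tested genes. X-linked Fndc3c1 was at log2 9.46 in WT and 6.37 in KO, Samt4 at 8.65 and 6.48 and Dnaaf6b at 7.97 and 6.30. These KO values lie near the lower quartile of that array, log2 6.17, and no measure of background was used here, so no fold is given for these 3 genes. X-linked 4930595M18Rik also lay lower in KO, and no fold is given for it either, because its KO value was near that level. Also X-linked, Ppp4r3c-ps was 4.96-fold lower in KO, Samt3 3.56-fold, the homeobox gene Rhox11 3.39-fold and the p21-activated kinase gene Pak3 3.28-fold. Y-linked Srsy was 4.15-fold lower. The autosomal genes named were Cpn1 at -2.44, Unkl at -2.12 and Zfp943 at -1.70. Higher in KO, with autosomal clone names left out, were Zfa-ps at 1.23, Il9 at 1.14, Rundc3a at 1.11, Malrd1 2.14-fold, the mitochondrial valyl-tRNA synthetase gene Vars2 at 1.05, Meis3 at 0.98, Bpifa6 at 0.93, Cntfr at 0.93, Prss30 at 0.91, the natriuretic peptide receptor gene Npr3 at 0.87, Nat8l at 0.86 and Hey2 at 0.83. Those from Meis3 on lay under 2-fold. The clone-named gene A530064D06Rik on chromosome 17, left out by that rule, lay higher than all of these, at 2.18. In the replicate pairs of pachytene arrays, 29 genes differed at least 2-fold in WT, 0 of them on X, and 183 in KO, with 24 X-linked genes higher in array 1.

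**Figure D2:**
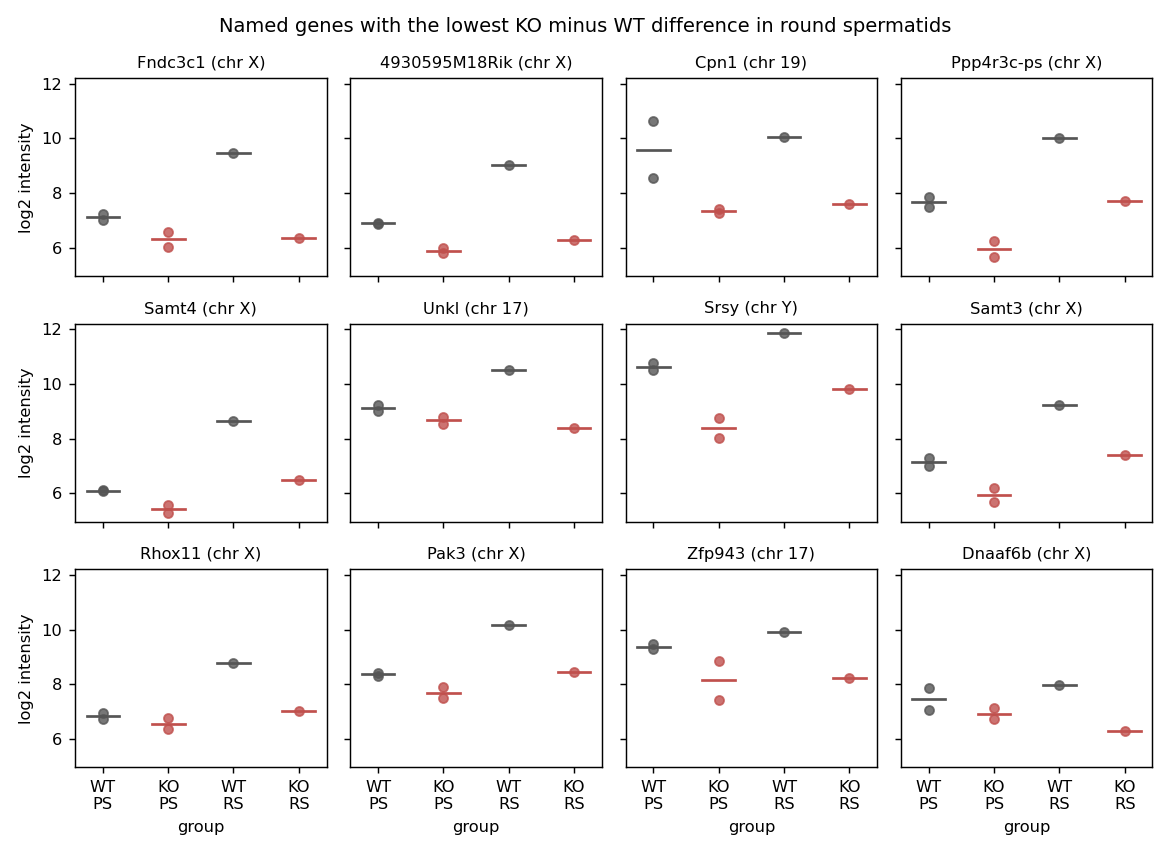
Log2 intensity of the 12 named genes with the lowest KO minus WT difference in round spermatids (autosomal clone names left out), with 1 point per array, a bar at the group mean, WT in grey and KO in red, for pachytene spermatocytes (PS, 2 arrays per genotype) and round spermatids (RS, 1 array per genotype). Fndc3c1 lies at 9.46 in WT and 6.37 in KO round spermatids.

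The lower X-linked genes lay mainly among those that increase after meiosis. Of 158 X-linked spermatid-high genes, 124 (78.5%) lay lower in the KO round spermatid array and 26 (16.5%) at least 2-fold lower, against 878 (78.7%) and 6 (0.538%) of 1116 autosomal spermatid-high genes. Median differences were -0.35 (quartiles -0.69 and -0.04) for X and -0.13 for autosomes. Between KO pachytene arrays 1 and 2, which are replicates, 24 of the same X-linked genes (15.2%) and 83 of the autosomal ones (7.44%) differed at least 2-fold, all higher in array 1, with medians of 0.56 and 0.44. Between the WT pachytene arrays 0 and 2 did, with medians of -0.05 and 0.02. The X-linked median was at percentile 0 of 10000 random lists of autosomal spermatid-high genes matched on expression, whose lowest median was -0.30. The other 466 X-linked genes had a median of 0.09, with 9 at least 2-fold lower, and all X-linked genes together a median of 0.03 against 0.05 for autosomes. Among random lists matched on expression, whose central 95% ran from 0.08 to 0.12, all X-linked genes were at percentile 0. Their difference from autosomes was -0.0144, and it was -0.0623 at a floor of log2 7 and -0.0652 with a second quantile normalization. From pachytene spermatocytes to round spermatids the X-linked spermatid-high genes had a median log2 rise of 1.73 in WT and 1.36 in KO, and the autosomal ones 1.45 and 1.26. In pachytene spermatocytes their KO minus WT medians were -0.05 and 0.03.

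**Figure D3:**
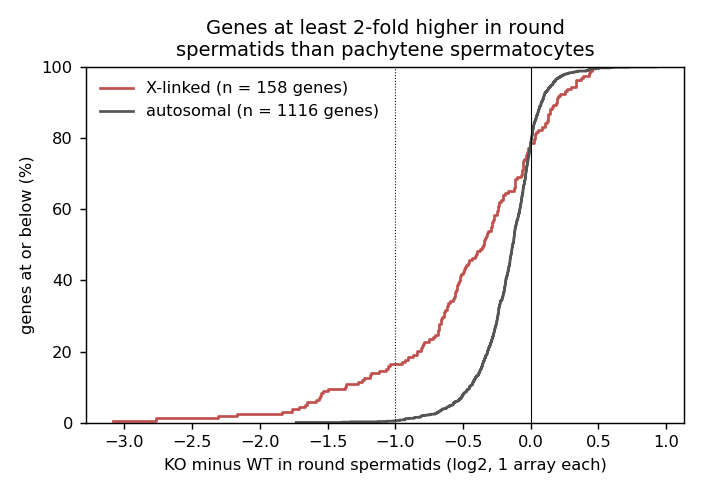
Cumulative share (%) of genes at or below each KO minus WT log2 difference in round spermatids (1 array each), for 158 X-linked (red) and 1116 autosomal (grey) spermatid-high genes, with a solid line at 0 and a dotted line at a 2-fold lower level in KO. At the dotted line the X-linked curve stands at 16.5% and the autosomal one at 0.538%, and at 0 they stand at 78.5% and 78.7%, with medians of -0.35 and -0.13.

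Among the lists, X-linked spermatid-expressed genes had a median of -0.37 in the KO round spermatid array (percentile 0 of random lists), with 22 of 28 lower. Samt3, Ssxb3 and 1700013H16Rik were at -1.83, -1.65 and -1.37, and Samt4, near the lower quartile of the array in KO, also lay lower. X-linked widely expressed genes were at -0.05 (percentile 0.06) and Y-linked genes at -0.20 (percentile 0.35), with Zfy1 at -0.94 and Zfy2 at -0.65. The DNA damage response was at -0.07 (percentile 2.15), with Brca1 at -0.49 and Abraxas1 at -0.45. Markers of other cells were at 0.22 for Sertoli cells (percentile 99.97), 0.22 for spermatogonia (percentile 99.96), 0.32 for peritubular and vessel cells (percentile 100) and 0.01 for macrophages and blood (percentile 1.35). Inha was at 0.60, Stra8 at 0.56, Igfbp7 at 0.50 and Sparc at 0.48. Spermatid differentiation genes were at -0.05 (percentile 2.52), with 49 of 62 lower, and Tnp1 was at -0.23. The other 9 lists lay within the central 95% of their random lists. With a second quantile normalization, X-linked widely expressed genes, the DNA damage response and macrophage and blood markers came to lie within it, and spermatid differentiation and p53 targets outside it. The DNA damage response also lay within it with no filter on dim genes, and macrophage and blood markers at a floor of log2 7, and in each of these cases spermatid differentiation lay outside it. The percentiles do not measure the spread between arrays. Between the KO pachytene replicates (array 1 minus 2) medians were 0.50 for X-linked spermatid-expressed, 0.12 for X-linked widely expressed and 0.59 for Y-linked genes. The DNA damage response was at 0.15 and spermatid differentiation at 0.25, all larger than between the genotypes. Sertoli, spermatogonial and peritubular markers differed less, at 0.06, 0.02 and -0.02. In the WT pair (array 1 minus 2) X-linked spermatid-expressed genes were at -0.05. Sertoli, spermatogonial and peritubular markers were at 0.11, -0.06 and 0.12 in that pair.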

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

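The tests of the excess of X-linked over rise-matched autosomal genes, of the X-linked genes in the KO pachytene arrays, of genes without a difference between the cell types and of KO pachytene array 2 were chosen only after the results were seen.

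For 5 lists and for the X-linked spermatid-high genes, the effect of genotype differed between the cell types in a test of the interaction with a preset correlation. Median interactions on the log2 scale were -0.29 for X-linked spermatid-expressed genes, -0.14 for X-linked widely expressed genes, -0.11 for spermatid differentiation, 0.19 for Leydig markers, 0.20 for peritubular and vessel markers and -0.33 for the X-linked spermatid-high genes. With an estimated correlation none of these 6 passed: adjusted p = 0.731 for spermatid differentiation and adjusted p = 0.700 for the other 4 lists, and p = 0.197 for the X-linked spermatid-high genes. Autosomal spermatid-high genes also had a negative median interaction of -0.18 (p = 2.14e-17 with the preset and p = 0.359 with an estimated correlation). All 624 X-linked genes together had a median of -0.06 (p = 1.45e-07 with the preset and p = 0.0329 with an estimated correlation).

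Lower values also appeared in 92 clusters that list several genes, all X-linked where a chromosome was assigned, which the comparisons do not use. Of these, 60 were at least 2-fold higher in round spermatids than in pachytene spermatocytes, with a median KO minus WT difference of -0.52 in round spermatids. Autosomal clusters that list several genes were not compared. Over all 92 clusters the median KO minus WT difference in round spermatids was -0.37, with 65 lower, 23 at least 2-fold lower and 0 at least 2-fold higher.

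X-linked spermatid-high genes lay lower in the KO round spermatid array, by a median of -0.35. Noise of dim genes is argued against, because those at log2 9 or more had a median of -0.32. A lower share of spermatids in the KO fraction stays open, also as the whole cause. The X-linked median lay -0.20 from that of autosomal genes matched on the rise and below the lowest of 10000 matched lists, at -0.24. Those lists draw genes as if independent, while the estimated correlation among the X-linked genes was 0.55, and each genotype has 1 array. Between the KO pachytene replicates (array 1 minus 2) the X-linked median also lay 0.11 above the autosomal one. Part or all of the difference may come from the share of spermatids, since the matched autosomal lists had a median of -0.15. Markers of Sertoli and peritubular cells also lay 0.22 and 0.32 higher in the KO round spermatid array. For the 35 X-linked genes at least 2-fold lower, differences in spermatid transcripts between the arrays stay open: in KO pachytene array 1 they lay at -0.42 and autosomal spermatid-high genes at 0.26 relative to the WT mean, but in array 2 both lay below it, at -0.59 and -0.18. A chance difference between single arrays stays open, with 1 array per genotype, and the loss of Rnf8 remains an untested candidate.

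Genotype differences of the same sign in both cell types were seen in 112 genes (1.5-fold or more on average, arrays not overlapping), 27 higher and 85 lower in KO. Chance agreement of arrays could produce a count of this size: exchanging WT pachytene array 1 for KO pachytene array 1 gave 123 genes, the highest of the other exchanges, and the correlation across genes of the differences in the 2 cell types, whose genes are not independent replicates, was 0.47 with the real genotypes and 0.48 with that exchange. Other values go against it: of the 63 genes at least 2-fold lower in KO round spermatids, 43 lay below WT on all pachytene arrays and 0 above (16.7% by chance for either), and of the 35 X-linked ones 27 lay below, though these genes are not independent of each other, so chance is not excluded. Genes that differed less than 1.5-fold between the cell types gave 47 with the real genotypes and at most 34 with an exchange, which leaves differences in spermatid transcripts between the arrays open.

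KO pachytene array 2 stood apart from the other 3 pachytene arrays. Fewer spermatid transcripts in that fraction stay open: its autosomal spermatid-high genes lay at -0.26 relative to the mean of the other 3, below the deviations of these 3 from the same mean (-0.09 to 0.17) but by less than the width of that range, 0.27, and KO pachytene array 1 lay farther from the mean of its other 3, at 0.33. More transcripts of somatic cells stay open as well: Leydig, peritubular and blood markers lay higher there than on each other pachytene array. For Sertoli markers the lowest median difference to another pachytene array was -0.0561. Their median level there, 8.33, was below those of the WT arrays (8.54 and 8.42) and of KO array 1 (8.71), so the lists do not all point 1 way. The loss of Rnf8 was not tested as an explanation, because both arrays are KO.

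For KO against WT over both cell types, the 10 splits of the 6 arrays into 3 against 3 are too few for a share under 0.05. At an adjusted p under 0.05, the real split passed 0 genes and the highest other split 1, so 10 of 10 splits gave as many. At an unadjusted p under 0.01, the real split passed 234 genes and the highest other 893, and 4 of 10 gave as many. The split with 893 has both round spermatid arrays on 1 side, unlike the real one. Among splits with 1 round spermatid array on each side, the highest other count was 583. A count several times the real one points to a structure of the samples, whose cause was not tested: the split with 893 sets KO pachytene array 2, with both round spermatid arrays, against the other 3 pachytene arrays.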

How the results depend on the processing

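The crossed pairing, the replicate block for cell type over both genotypes and its lists, the restriction of spermatid-high genes to log2 9 or more and the addition of clusters that list several X-linked genes were chosen only after the data were seen. Apart from leaving out an array, 99 alternatives were run, of which 83 stayed within 1.5 times the count, within the spread of replicate pairs or, for 6 of the X-linked set in pachytene spermatocytes, on the same side of its test, 16 moved and 0 reversed. For KO against WT over both cell types, 0 genes became 1 with arrays centred on the autosomal median, 8 with every named cluster, 2 with a trended and robust prior, 3 at an adjusted p under 0.1 and 2 with the replicate block. In pachytene spermatocytes 0 genes became 43 with the replicate block (10 higher, 33 lower) and 88 with crossed pairing as the block (18 higher, 70 lower), and the interaction 0 became 1 with the block. The values give no sign that the replicate numbers pair the arrays, with deviations of same-numbered arrays correlated at -0.23 across genes, but 2 arrays per genotype cannot settle it. The block also ended the call of the peritubular and vessel markers in pachytene spermatocytes (6 lists in place of 7). For cell type it gave 3602 genes in WT, 2929 in KO and 5375 over both genotypes, within 1.5 times the counts without it, and the same 7 lists. In round spermatids the 69 genes became 343 at 1.5-fold (70 higher, 273 lower) and 0 in the fit with the spread of the pachytene pairs. In pachytene spermatocytes the X-linked minus autosomal difference was 0.0287 and became 0.0076 with a second quantile normalization. In round spermatids it moved from -0.014 to -0.0623 at a floor of log2 7 and -0.0652 with a second quantile normalization. The X-linked minus autosomal spermatid-high difference moved from -0.22 to -0.32 with several-gene clusters added to the X-linked genes only. Of the lists, 7 in pachytene spermatocytes became 5 at a floor of log2 7 and with arrays centred on the autosomal median, both without Leydig markers and the DNA damage response, and 2 with the second quantile normalization, and with an estimated correlation 0 passed there and 0 between the cell types. In round spermatids 8 lists became 7 with the second quantile normalization, of which 5 were shared. The cause was not tested in these cases. Rnf8 has 1 cluster, so using every cluster gives no other value.

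Leaving out each array gave 0 to 2 genes in pachytene spermatocytes, 0 to 21 over both cell types, 0 for the interaction, 1404 to 5511 for cell type in WT, 1646 to 3883 in KO and 2786 to 8849 over both genotypes, 3 to 8 lists in pachytene spermatocytes, 7 to 8 between the cell types and an X-linked minus autosomal difference of 0.0037 to 0.0202 in pachytene spermatocytes. Fewer arrays enter each such fit. The 8849 came without KO pachytene array 1, the 3 lists without WT pachytene array 2. Of the 7 lists in pachytene spermatocytes, 6 and 2 remained without WT array 1 or 2, and 2 and 4 without KO array 1 or 2. How far signal over background limits dim genes was examined only through the intensity floor.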

Other observations

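The comparison of all chromosomes for same-sign differences was chosen only after the test of the genes nearest to Rnf8 had been seen.

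Chromatin genes changed in both directions between the cell types. Of 38 histone variant and nucleosome replacement genes, 10 rose and 10 fell in round spermatids (10 and 10 adjusted over the list alone; camera adjusted p = 0.918). H1f6 fell by 2.78, while the spermatid histone gene H2ab1 rose by 1.63, the chromatin remodeller Chd5 by 1.39 and Camk4 by 1.87. Of 47 histone acetylation genes, 9 rose and 21 fell (12 and 21 adjusted over the list alone; camera adjusted p = 0.270), with the acetyltransferase Kat2b up by 1.78, Msl3 by 1.61 and Cdyl2 by 1.53 and Trrap down by 1.56. Between genotypes H2ab1 lay at -1.11 in pachytene spermatocytes (adjusted p = 0.414) and -0.75 in round spermatids.

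Rnf8 lies on chromosome 17, and a part of that chromosome from another mouse strain, carried along with the targeted allele, is a candidate source of same-sign genotype differences. The test set before its result was seen argues against a region of the 100 tested genes nearest to Rnf8, which held 0 same-sign differences, no more than the median window, although 0 of 100 would occur in 14.9% of cases at the rate of the whole chromosome. Chromosome 17 as a whole had 16 same-sign genes of 849 (1.885%), against at most 0.623% on any other autosome, and 4 when WT and KO pachytene array 1 were exchanged. Of the 16 genes, 11 lay among the 424 tested genes on the side of the chromosome that holds Rnf8. The nearest to Rnf8 lay 61 tested genes away. Counted in tested genes from Rnf8, all but Ehd3, at 465, lay between -298 and 318. Whether their density falls with distance from Rnf8 was not tested, so a longer part of the chromosome from another strain stays open. The 16 genes include Zfp942, Zfp943, Unkl, Flywch2, Prss30, Noxo1, C4b, Ehd3 and A530064D06Rik, named after their values were seen. A530064D06Rik was at 2.09 in pachytene spermatocytes and 2.18 in round spermatids. Whether expression or probe binding at strain variants differed was not tested.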
